A study of Drosophila melanogaster with 9 samples.

How the data were processed

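Poly(A) RNA of whole flies was made into strand-keeping libraries and sequenced on an Illumina NovaSeq in paired ends of 51 cycles, per the labels. The authors deposited a workbook with a raw count table, a table of their own comparison, normalised and regularised-log tables, a sample sheet and a gene annotation sheet. The submitters' processing notes name cutadapt 1.16, STAR 2.6.1b, featureCounts 1.6.3 and DESeq2 1.20.0 and 1.22.2, and the genome builds BDGP6 and dm6, without their roles. The settings of alignment and counting, the strand setting and the treatment of reads that fit several genes are not given in the sources used here.

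The deposited sheet named raw counts holds counts per gene and library, whole numbers whose totals differ between libraries, and each of the 9 columns carries the library number of a title. They list 14865 of the 17737 genes in the annotation sheet. The authors' comparison holds a log2 fold change with its standard error and p-values, raw and adjusted, with the column names of DESeq2 per the file headers, and whether the log2 values were shrunken is not stated. These deposited log2 values and p-values were only set beside the new fit. The normalised and regularised-log tables were not used here. Gene symbols and coordinates were taken from the authors' annotation sheet.

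Libraries were grouped by the genotype in their titles, 5 control and 4 E78A mutant, and replicates were numbered in accession order. The genotype tag names the opposite genotype for 4 libraries. The rule fixed before the data were examined was to use all 9 libraries if the authors' sample sheet gave every one the genotype of its title, and otherwise the 5 whose title and tag agree. The sheet disagreed with 0 titles. Library totals ran from 16556267 to 19093675 counts. Each value per library rests on these counts. PCR copies were not marked, and floors cover counting error only. The interval of Eip78C also holds the spread between libraries, and bootstrap intervals draw genes.

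Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest, genotype as the term), which tested 13274 genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The biological coefficient of variation was 15%. The interval of Eip78C uses 7 residual degrees of freedom. Log-CPM values for gene lists and principal components used a prior count of 2, and CPM values use TMM-scaled library sizes. Fold changes against a group at 0 use a floor of 3 counts over the group. The sample sheet gives replicate numbers that the titles do not. Deviations from the group means of libraries with the same number correlated at 0.207, 0.214, 0.210 and 0.277 across genes, each above its highest value with another number (at most 0.0402), so the numbers were taken to pair 4 control and 4 mutant libraries, with control replicate 3 left without a partner. The fit with that number as a block, and camera with an estimated correlation on it, were added after the data were seen, as was an exact sign-flip test of the log2 ratios of summed CPM per list over the 4 pairs, adjusted over the 29 lists.

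There were 29 gene lists with 958 entries, fixed before the data were examined, of which 870 matched the annotation sheet by symbol, 44 a current symbol and 22 a synonym, and 22 did not match. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The genes named are Eip78C, the 8 highest and the 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM in the higher group and no overlap of libraries, and the 3 members with the smallest p of each digestion, lipid or hormone list and of each other list that passed camera. A gene outside this rule is said to have been named after its values were seen.

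Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no low-count filter, a filter of 1 CPM in 4 libraries, each library left out in turn, grouping by genotype tag, the 5 libraries whose labels agree, an adjusted p under 0.01, a 2-fold minimum, camera without gonad markers and camera with an estimated correlation. Fits were also run on 100 of the 126 splits of the libraries into groups of 5 and 4, the real split included. The script was tested on simulated data. Counts for 13274 genes were drawn from the observed means, spreads and library sizes, in 5 draws of the control and mutant comparison. Each gene was drawn independently and without pairs, and 200 genes with a mean of at least 1 CPM were changed. Of the genes changed 1.5-fold, 56.4% were recovered, of those changed 2-fold 91.2%, 4-fold 99.6% and 8-fold 100%, and 6.77% of the calls were false. In the same comparison over 13274 genes, a list lowered by a log2 value of -0.4 was called in 5 of 5 draws, with 1 unchanged list called as well. Members of a real list vary together, and camera called at least 3 lists in 98 of the 100 splits. The simulation therefore does not show how often camera calls unchanged lists in these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.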

Results

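Whole Drosophila melanogaster flies were sequenced as poly(A) RNA 8 days after eclosion in 2 genotypes, a control and a mutant for E78A. E78A is a nuclear receptor made from the gene Eip78C, and the series was set up to ask how it bears on fat uptake in the gut and on lipid levels of the body. Flies of both genotypes were kept on food with 8% yeast and 9% sugar. There were 5 control and 4 mutant libraries. Nothing in the labels says how many flies went into a library or whether libraries came from separate crosses, so p-values measure the spread between these samples, which may be technical. The totals ran from 16556267 to 19093675 counts per library over 14865 listed genes, and 13274 genes were tested. Replicates of a group differed by more than sampling noise (chi-square over degrees of freedom from 17.3 to 42.9), so no library was treated as a copy of another.

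The sex of the flies is not given in the labels. The 3 yolk protein genes summed to 12.2 ± 2.40 CPM in the controls (SD, n = 5) and 9.90 ± 3.42 CPM in the mutants (SD, n = 4). Markers of the male accessory gland and ejaculatory tissue summed to 17400 ± 2531 and 17820 ± 2843 CPM. In every library the yolk proteins were at 16.1 CPM or less and these male markers at 14310 CPM or more. By these markers the flies were mainly or all male, so the results do not bear on females. The first principal component of all tested genes held 30.3% of the variance and parted the genotypes, with the mutant libraries at 17.4 and above and the controls at -7.24 and below. Control replicate 3 lay farthest out, at -32.5. For 4 libraries, control replicates 4 and 5 and mutant replicates 3 and 4, the title and the genotype tag named opposite genotypes. The authors' sample sheet gave all 9 libraries the genotype of their titles, which was used here. It names the genotype of the controls w1118 and that of the mutants E7818.37.

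The targeted gene came first. Eip78C (FBgn0004865, chromosome 3L, 21226609 to 21266503, plus strand) was at 10.6 ± 2.86 CPM in the controls (SD, n = 5) and 10.7 ± 1.45 CPM in the mutants (SD, n = 4), and thus was not lower in the libraries labelled mutant. The control libraries, replicates 1 to 5, held 8.57, 10.4, 8.94, 15.6 and 9.60 CPM, and the mutant libraries 12.4, 8.86, 10.8 and 10.6 CPM, from 149 to 307 counts each. The log2 fold change, mutant over control, was 0.00467 (SE 0.176, edgeR adjusted p = 0.993), with a 95% interval from -0.412 to 0.422, whose lower end is a level 1.33-fold lower in the mutants. The authors' deposited table gave 0.00509 (SE 0.171, adjusted p = 0.993). These are counts over the whole gene, and the labels do not say which part of it the mutation alters, so they do not check the genotype labels if transcripts outside that part remain. CG43218, a short gene inside Eip78C on the same strand (21258020 to 21258758), had 84 counts over the mutants, 11.5% of the 729 of Eip78C, and 139 over the controls, and how reads over both genes were assigned is not given in the sources used here.

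**Figure D1:**
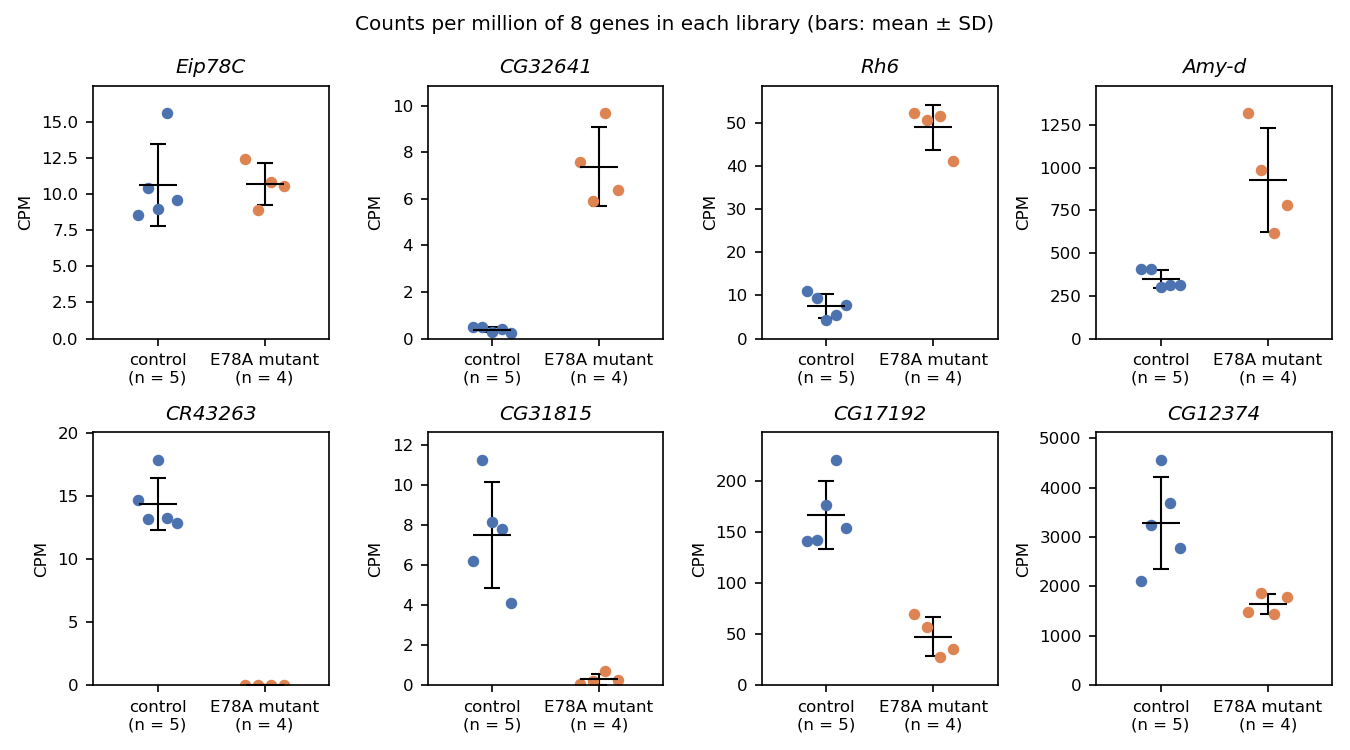
CPM (linear axis from 0) of 8 genes in each control library (blue, n = 5) and E78A mutant library (orange, n = 4), with black bars at the mean ± SD. Eip78C overlaps between the genotypes at 8.57 to 15.6 CPM, while CG32641, Rh6 and Amy-d are higher and CR43263, CG31815, CG17192 and CG12374 lower in every mutant library than in any control library.

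Among the genes higher in the mutants, Rh6, the opsin of a subset of colour-sensing photoreceptors, rose from 7.58 ± 2.83 to 49.0 ± 5.26 CPM (log2 fold change 2.69, SE 0.22, adjusted p = 5.62e-05), and Amy-d, an alpha-amylase that digests starch, rose from 349 ± 53.8 to 926 ± 302 CPM (1.41, SE 0.19, adjusted p = 0.00195). Among called genes with at least 5 CPM in the higher group and no overlap of libraries, the protein-coding gene CG32641 had the highest log2 fold change, 4.24 (SE 0.25, adjusted p = 4.05e-06), from 0.383 ± 0.122 to 7.38 ± 1.69 CPM. In all, 94 genes were higher in the mutants at an adjusted p under 0.05, of which 78 were protein-coding, 14 non-coding and 2 pseudogenes, and 44 of them differed by 2-fold or more.

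Rh6 (FBgn0019940) lies on 3R at 15483158 to 15484699, Amy-d (FBgn0000078) on 2R at 17124764 to 17126369 and CG32641 (FBgn0052641) on X at 13184478 to 13184996. The next highest within those limits were CG43401 (3.08), CR43719 (2.87), CR45600 (2.85), CG31832 (2.75), the lysozyme pseudogene LysC (2.20) and CG34283 (1.86). By the rule that chose them, none of these 8 genes, Rh6 and CG32641 included, could have a control library as high as any mutant library. CG32641, CR43719, CG31832 and CG34283 lie opposite Lgr4, Plc21C, GABA-B-R1 and ChAT on the other strand. CR45600 shares its strand with CG6912, and LysC overlaps mwh on its own strand and LysD on the other. The kit keeps strand, but the strand setting of the counting is not given in the sources used here, so reads of such partners cannot be told apart. Amy-d has a near-identical copy, Amy-p, and is uncertain for that reason. It also lies among other called genes. On 2R from 16000001 to 18000000, 8 of 316 tested genes were called, 6 higher and 2 lower. All 8, Amy-d and its neighbour Cda9 (1.90, named after its values were seen) included, lay between 17124764 and 17482118. A local difference between the stocks cannot be told apart from an effect of E78A on Amy-d.

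Among the genes lower in the mutants, CG17192, a predicted lipase, fell from 167 ± 33.5 to 47.7 ± 19.4 CPM (log2 fold change -1.81, SE 0.25, adjusted p = 0.00211), and CG31205, a serine protease gene, fell from 23.6 ± 5.32 to 7.20 ± 1.81 CPM (-1.71, SE 0.21, adjusted p = 0.00119). The non-coding RNA CR43263 had 1303 counts over the controls (14.4 ± 2.08 CPM) and 0 over the 4 mutants, which is at least 327-fold lower with 3 counts over the group as the floor. Its neighbour CR45346 (2L, 1214649 to 1215293) went from 2.42 to 0 CPM (edgeR adjusted p = 0.00335). Of other called genes nearby, CG5139 (-0.92) and CG43348 (-2.52) were lower and CG5397 (0.76) higher. These 4 were named after their values were seen. A stretch that differs between the stocks cannot be told apart from lost expression here. The protein-coding gene CG31815 fell from 7.50 ± 2.64 to 0.292 ± 0.277 CPM (-4.64, SE 0.46, adjusted p = 0.000271). In all, 123 genes were lower, of which 93 were protein-coding, 27 non-coding and 3 pseudogenes, and 64 of them differed by 2-fold or more.

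CG17192 (FBgn0039472) lies on 3R at 27017180 to 27018287, CG31205 (FBgn0051205) on 3R at 20731631 to 20732707, CR43263 (FBgn0262944) on 2L at 1216854 to 1217785 and CG31815 (FBgn0051815) on 2L at 16605822 to 16607321. Among called genes with at least 5 CPM in the higher group and no overlap of libraries, the others with the lowest log2 fold changes were the pseudogene CR33319 (-5.52), CR43808 (-3.94), the pseudogene CR33318 (-1.74) and CR46007 (-1.65). CR33319, CG17192 and CR46007 lie opposite CG9270, RYa-R and CG34114, CG13282, named with the lipases, lies opposite AspRS-m, and CG31815 shares its strand with CG42389, so the limit on overlapping genes holds for them too.

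The 217 calls of both directions made up 1.63% of the tested genes, and 2004 genes had an unadjusted p under 0.05. The libraries of the 2 genotypes did not overlap for 818 tested genes (6.16%, against 1.59% by chance) and for 214 of the called ones. With the pairs of the authors' sample sheet as a block, a choice made after seeing the data, edgeR called 248 higher and 269 lower genes, 208 of the 217 among them. DESeq2 on the same counts called 235 and 265, with all 217 among them, and the authors' deposited table held 239 and 267. The authors' deposited table shared 216 of the 217 calls, each with the same sign. With the 5 libraries whose labels agree, 13 were higher and 8 lower, and grouped by the genotype tag edgeR called 0 genes, with 171 at an unadjusted p under 0.05.

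Of the 12 lists of digestion, lipid and hormone genes fixed beforehand, only the digestive proteases passed camera with a preset correlation (adjusted p = 8.8e-06), and they did not pass with an estimated correlation (adjusted p = 0.956). The 45 tested members summed to 21510 ± 2979 CPM in the controls and 15890 ± 2476 CPM in the mutants, 35 had a negative log2 fold change, and the median was -0.35. CG31205, CG12374, CG17633, CG8560, Jon99Ciii and Bace were lower, and CG18417 was higher. CG12374, a predicted carboxypeptidase, fell from 3282 ± 928 to 1643 ± 211 CPM (-0.998, SE 0.19, adjusted p = 0.0178), and CG18417 rose from 10.8 ± 0.958 to 19.3 ± 2.63 CPM (0.84, SE 0.11, adjusted p = 0.00195). Adjusted over the list alone, 17 members were lower and 1 was higher. The sum was lower in the mutant of all 4 pairs of the sample sheet, at 17910, 17760, 15230 and 12670 CPM against 19670, 21860, 23150 and 17600. The mean of the log2 ratios was -0.378 (exact sign-flip test over the 4 pairs, two-sided p = 0.125, the smallest it can give, adjusted p = 0.604, chosen after a paired test assuming normal values had been seen). With the pairs as a block the median was -0.386 (adjusted p = 3.94e-07, and 0.912 with an estimated correlation), and 17 members were lower and 1 was higher over all genes. A median as far from 0 came from 6 of 100 splits of the 9 libraries, the real one included, and from 1 of the 10 other drawn splits that part all pairs. CG17633, Jon99Ciii, Bace and CG8560 were named after their values were seen, and the calls of the last 3 (adjusted p = 0.0494, 0.0486 and 0.0473) held in 5, 8 and 7 of the 16 alternatives that keep the grouping by title, while those of CG12374 and CG17633 ended without mutant replicate 3 or 4.

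Among the 40 tested lipase genes, CG17192 and CG13282 (-0.51, SE 0.12, adjusted p = 0.0488) were lower and 0 were higher, CG13282 in 6 of 16 alternatives, the same 2 lower when adjusted over the list alone, with a list median of -0.0402 (camera adjusted p = 0.666). With the replicate block 3 lipase genes were higher and 3 lower. CG18284 had a log2 fold change of 0.32 (SE 0.10, adjusted p = 0.15, from 0.00669 with the replicate block to 0.893 over 16 alternatives). The gut lipase gene mag, named after its values were seen, had 151 ± 32.2 and 103 ± 47.5 CPM (-0.55, SE 0.25, adjusted p = 0.325, from 0.0401 without mutant replicate 2 to 0.91 over the same alternatives). In carbohydrate digestion, Amy-d was the 1 member of 26 called, also when adjusted over the list alone, and with the replicate block 2 members were higher and 3 lower, while CG9701 and Treh had log2 fold changes of 0.35 and 0.17. The median of that list was -0.0651, its mean 0.0217 and its camera direction up (adjusted p = 0.785).

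Lipid transport and storage genes did not pass the test as groups, and without the replicate block 1 member was called over all genes. That was CG4594 of the fatty acid beta-oxidation list, which fell from 8.66 ± 0.701 to 5.08 ± 0.357 CPM (-0.77, SE 0.12, adjusted p = 0.00418, 1 of 35 members, also when adjusted over the list alone). Its neighbour CG4592 had -0.47 (adjusted p = 0.171) and Mfe2 0.19 (adjusted p = 0.341). Among 27 genes of sterol and lipid uptake, Npc2a, which carries sterols, had 54.1 ± 7.65 and 74.2 ± 8.73 CPM (0.46, SE 0.11, adjusted p = 0.0629, from 0.00763 to 0.595 over 16 alternatives, called in 3 with the replicate block among them). It was the 1 member higher when adjusted over the list alone. The fatty acid transporter Fatp had 0.50 (adjusted p = 0.12, from 0.0197 with DESeq2 to 0.905, called in 3 of 16 alternatives, with log2 fold changes from 0.22 to 0.62), and the CD36-family gene emp -0.34 (adjusted p = 0.187, from 0.0471 with the replicate block to 0.905). Among 23 genes of triacylglyceride synthesis and droplets, CG1946 had 5.84 ± 1.43 and 2.71 ± 1.02 CPM (-1.10, SE 0.25, adjusted p = 0.0528, from 0.0015 to 0.355 over 16 alternatives, called in 4 with the replicate block among them) and was the 1 member lower when adjusted over the list alone. In the same list wun2 had 0.42 and CG15450 -0.28.

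No member was called, over all genes or over the list alone, among 9 lipoprotein genes (NLaz 0.21, LpR1 -0.21, GLaz -0.20), 13 genes of triacylglyceride mobilisation (CG2064 0.34, CG1882 0.16, AkhR -0.29) or 35 genes of fatty acid synthesis (CG9458 -0.39, SREBP 0.24, CG30008 -0.37). The camera adjusted p of these lists was 0.724, 0.499 and 0.785, and those of sterol uptake, droplets and beta-oxidation were 0.785, 0.989 and 0.785. The summed lipoprotein genes were at 6592 ± 851 CPM in the controls and 6012 ± 657.6 CPM in the mutants, and lower in the mutant of all 4 pairs of the sample sheet, at 6391, 6596, 5112 and 5950 CPM against 7404, 7400, 5794 and 6734. The mean of the log2 ratios was -0.184 (exact sign-flip test over the 4 pairs, two-sided p = 0.125, the smallest it can give, adjusted p = 0.604 over 29 lists). That test was chosen after a paired test assuming normal values had been seen to call this list and no other, and with 4 pairs it cannot pass 0.05 for any list. In the same sums 6 of the 29 lists went one way in all pairs against 3.62 if directions were random. Most of this sum is apolpp, a gene named after its values were seen, at 4955 ± 808.5 and 4273 ± 777.6 CPM (-0.21, SE 0.14, adjusted p = 0.516, from 0.0304 with the replicate block to 0.948 over 16 alternatives, called in 1), while 6 of the 9 members and the list median of 0.147 were positive. With the block, 1 lipoprotein gene was lower, as were 3 of sterol uptake, against 2 higher there. The 3 lower were fabp (-0.46, edgeR adjusted p = 0.00128), CG8628 (-0.65, adjusted p = 0.0247) and emp. The 2 higher were Npc2a and Npc2h (0.25, adjusted p = 0.0277). The genes fabp, CG8628 and Npc2h were named after their values were seen. The sterol uptake and droplet lists had medians of 0.0136 and 0.0340, both with a mean of -0.0298 and a camera direction up.

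The 3 lists of hormone genes likewise held no call over all genes. Outside these lists, the hormone gene ETH, described below, was lower. The hormone receptor gene CrzR, named after its values were seen, was higher (0.35, SE 0.07, edgeR adjusted p = 0.0301). Of 18 nuclear receptors, dsf, a regulator of sexual behaviour, had 1.73 ± 0.367 and 0.777 ± 0.174 CPM (-1.15, SE 0.26, adjusted p = 0.0535), the 1 member lower when adjusted over the list alone. Hr96 and Eip75B had log2 fold changes of 0.20 and 0.27. The summed nuclear receptors were higher in the mutant of all 4 pairs of the sample sheet (mean log2 ratio 0.0848, exact sign-flip test, two-sided p = 0.125, adjusted p = 0.604). Eip71CD (-0.32), Eip75B and ImpL3 (0.22) had the smallest p of the ecdysone list of 28. Those of the insulin and adipokinetic list of 23 were Ilp8 (-0.74), Ilp3 (0.44) and AkhR. Both lists were without a call when adjusted over the list alone. The 3 lists had camera adjusted p values of 0.499, 0.770 and 0.785. The insulin list's median was 0.0492, its mean -0.0330 and its camera direction down.

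**Figure D2:**
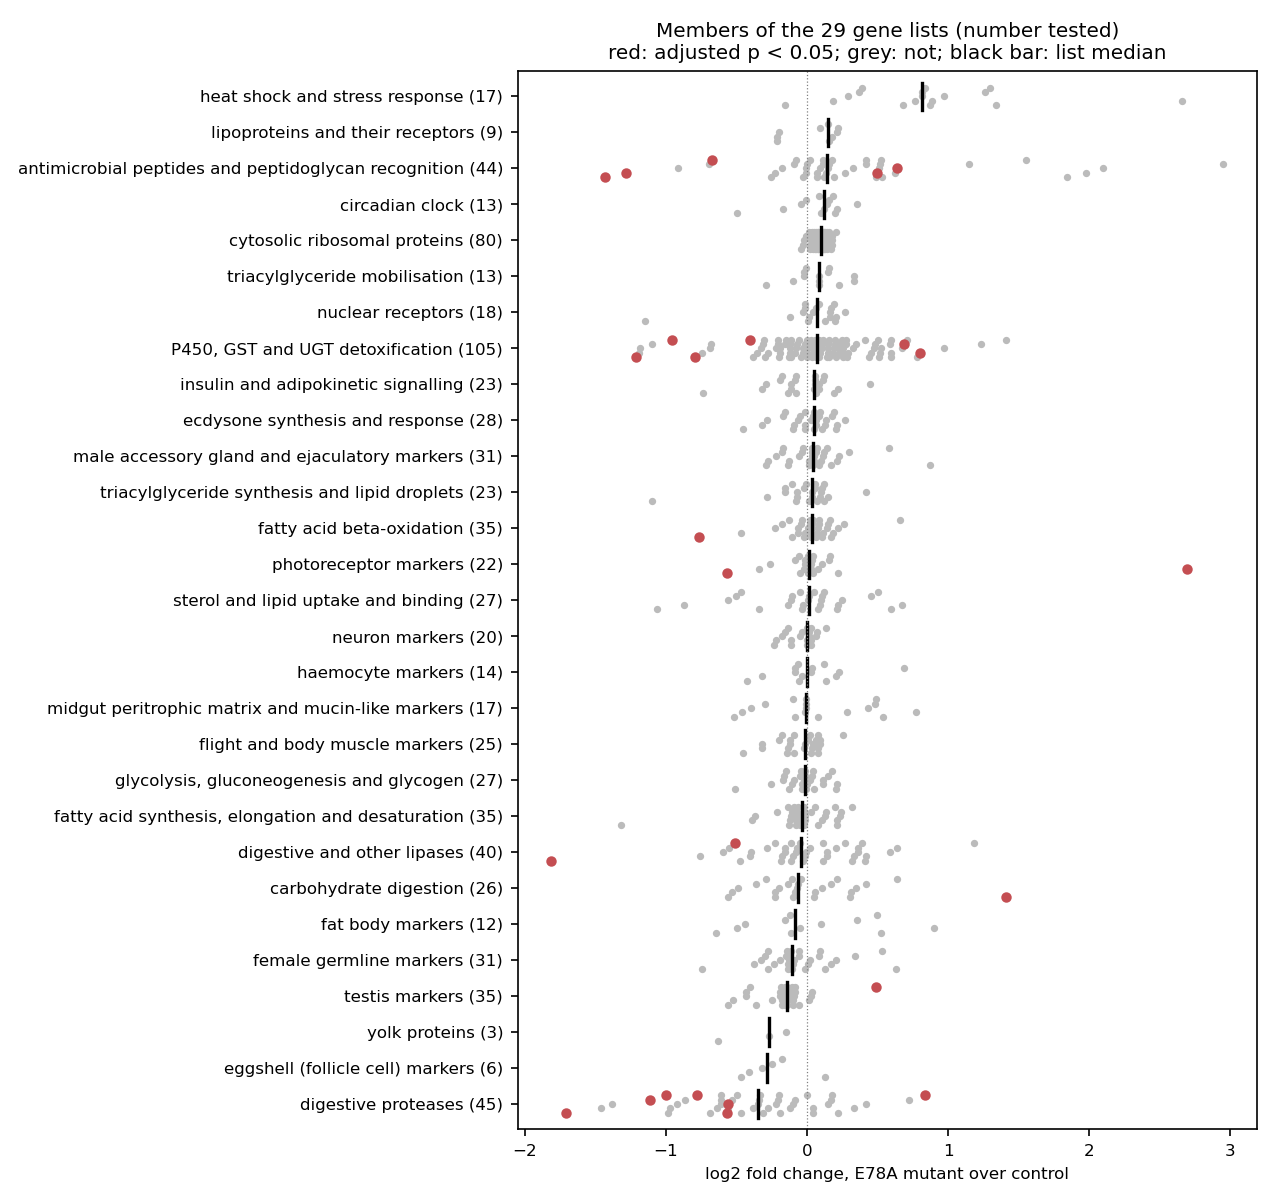
Log2 fold change, mutant over control, of every tested member of the 29 gene lists, with the number tested in brackets, members at an adjusted p under 0.05 in red, the others in grey, and a black bar at the list median. The digestive proteases have the lowest median, -0.35, and heat shock genes the highest, 0.815, with no heat shock gene called.

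Among the other lists, the 80 cytosolic ribosomal protein genes had a median of 0.101 with 76 positive, but no member was called, over all genes or over the list alone, with RpL3 (0.20), RpL4 (0.18) and RpS19a (0.18) at the smallest p. The list passed camera with a preset correlation (adjusted p = 5.07e-07) and not with an estimated correlation (adjusted p = 0.956), nor fry in one direction (adjusted p = 0.856). Its sum ran from 42650 to 47660 CPM in the controls and from 43620 to 48990 CPM in the mutants, and was higher in the mutant of 3 of the 4 pairs (control replicate 2 at 47660, its partner at 47410). The 35 testis markers had a median of -0.144 with 31 negative (adjusted p = 0.000222, and 0.956 with an estimated correlation). In that list Mst84Db rose from 106 ± 14.2 to 149 ± 12.4 CPM (0.49, SE 0.10, adjusted p = 0.0275), against the list's direction and in 10 of 16 alternatives, and ProtB (-0.43) and fzo (-0.36) were not called, ProtB being called with the replicate block and in 3 of 16 alternatives in all. Over the list alone 1 testis gene was higher and 2 were lower. The summed testis markers were 11860 ± 1512 CPM in the controls and 10900 ± 116 CPM in the mutants. Control replicate 3 was at 14460 CPM and the other controls at 10550 to 11610, against 10810 to 11060 in the mutants, and control replicate 2 lay below its partner of the sample sheet (10550 against 10920). Without control replicate 3 the median was -0.0682 (adjusted p = 0.0214), and with the replicate block -0.0671 (adjusted p = 0.028, and 0.912 with an estimated correlation).

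Immune and detoxification genes held calls in both directions. The digestive lysozyme genes LysB (-1.43), LysD (-1.28) and LysE (-0.67) were lower, while the short secreted immune peptide genes CG15068 (0.64) and IM4 (0.49) were higher, in a list of 44 (camera adjusted p = 0.266). Among 105 cytochrome P450, glutathione S-transferase and UDP-glycosyltransferase genes 2 were higher, GstD10 (0.80) and Ugt36Bc (0.69), and 4 were lower, GstD3 (-0.79), Cyp4ad1 (-1.21), Cyp4p2 (-0.96) and Ugt35a (-0.40) (camera adjusted p = 0.295). Adjusted over each list alone, 3 immune genes were higher and 3 lower, and 7 detoxification genes were higher and 7 lower. With the replicate block 5 immune genes were higher and 3 lower over all genes, and 5 detoxification genes were higher and 7 lower. The summed immune genes were higher in the mutant of all 4 pairs, at 3612, 2709, 2659 and 2747 CPM against 2609, 2702, 2302 and 2722. The pairs of mutant replicates 2 and 4 were nearly level, so the mean rests on the others. The mean log2 ratio was 0.174 (exact sign-flip test, two-sided p = 0.125, the smallest it can give, adjusted p = 0.604). The genes of both lists given by name here were named after their values were seen, and the lysozymes and the glutathione S-transferases lie in clusters of close copies that can share reads. The opsin Rh2 of the simple eyes was lower (-0.56, SE 0.09, adjusted p = 0.00701), the other call besides Rh6 among 22 photoreceptor markers. Adjusted over the list alone, Rh5 (-0.34, adjusted p = 0.133 over all genes, from 0.0231 with the replicate block to 0.886 over 16 alternatives) was lower as well, and it and Rh2 were named after their values were seen. Rh5 was at 62.69 ± 8.187 CPM in the controls and 49.65 ± 3.435 CPM in the mutants. Rh6 was thus far below Rh5 in the controls (7.58 ± 2.83 CPM) and near it in the mutants (49.0 ± 5.26 CPM). Which group departs from the usual level was not tested.

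Heat shock genes had a median of 0.815 with 16 of 17 positive and none called (camera adjusted p = 0.157). Their summed level ran from 2210 to 8393 CPM in the controls and from 3528 to 14420 CPM in the mutants, and was higher in the mutant of all 4 pairs (mean log2 ratio 0.452, exact sign-flip test, two-sided p = 0.125, adjusted p = 0.604). The list passed camera without mutant replicate 2, mutant replicate 3 or control replicate 5. With the replicate block 3 members were called higher, and the list had a median of 0.518 and an adjusted p of 0.000443, and the accessory gland markers a median of 0.131 and an adjusted p of 0.0125. With an estimated correlation both had an adjusted p of 0.912 under the block and 0.956 without it, and 0 lists passed camera under the block, with 1 at an unadjusted p under 0.05. Without the block, the accessory gland list had a median of 0.0407 (adjusted p = 0.564). The remaining marker lists did not pass camera. Their medians were -0.283 for eggshell (adjusted p = 0.492), -0.270 for yolk proteins (0.499), -0.105 for female germline (0.492), -0.0834 for fat body (0.720), -0.0112 for muscle (0.666), 0.0166 for photoreceptors (0.770), 0.00011 for neurons (0.499), -0.00252 for haemocytes (0.785) and -0.00351 for the midgut peritrophic matrix (0.720). Glycolysis had -0.0145 (0.785) and the circadian clock 0.119 (0.525). Adjusted over each list alone, the gene to (-0.50) was lower in the circadian and fat body lists and Muc68D (-0.51) in the peritrophic matrix list, and no member of the other lists of this paragraph was called. Those 2 genes were named after their values were seen. Over all genes they had adjusted p values of 0.0512 and 0.0985 and were called in 4 and 3 of 16 alternatives, the replicate block among them (0.0035 to 0.141, and 0.00324 to 0.905). With the block 1 circadian gene was higher and 1 lower, 2 fat body genes were lower, and 1 peritrophic matrix gene was higher and 1 lower. It also called 1 gene lower in each of the glycolysis, muscle, neuron and haemocyte lists. In the accessory gland list 1 gene was higher, and among photoreceptor markers 1 was higher and 3 lower. The median, mean and camera direction differed in sign for fat body, neurons, haemocytes and the peritrophic matrix. At least 3 lists passed camera with the preset correlation in 98 of 100 splits of the libraries. With an estimated correlation 0 lists passed, 0 also at an unadjusted p under 0.05, and fry called 0 lists as moving one way, with 1 at an unadjusted p under 0.05.

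Tested for change in either direction with fry, 6 lists passed: detoxification and photoreceptors (adjusted p = 1.52e-05 each), digestive proteases (0.000252), lipases (0.00179), antimicrobial genes (0.00336) and nuclear receptors (0.0431). This test does not compare a list with the other genes, of which many differed: 15.1% of all tested genes had an unadjusted edgeR p under 0.05. It was not run on the splits or with the block. Of the 22 photoreceptor markers 20 were not called, nor was any of the 18 nuclear receptors. A pass thus does not set a list apart from the rest.

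Called genes were spread unevenly over the chromosome arms. There were 85 on 3R (2.58% of its tested genes), 54 on 2L (2.09%), 35 on 3L (1.36%), 32 on 2R (1.2%) and 11 on X (0.541%), while only 1 of 265 tested genes within 1000 kb of Eip78C was called. Called genes were placed at random 10000 times among genes of like expression and type. These placements put a mean of 54.4 on 3R and 32.1 on X (two-sided permutation p adjusted over the 5 arms 0.0005 for both arms), and 43.3 on 2L, 42.8 on 2R and 42.7 on 3L (adjusted p = 0.109, 0.109 and 0.223). The placements move genes one by one while called genes lie close together, so these p-values can be too small.

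**Figure D3:**
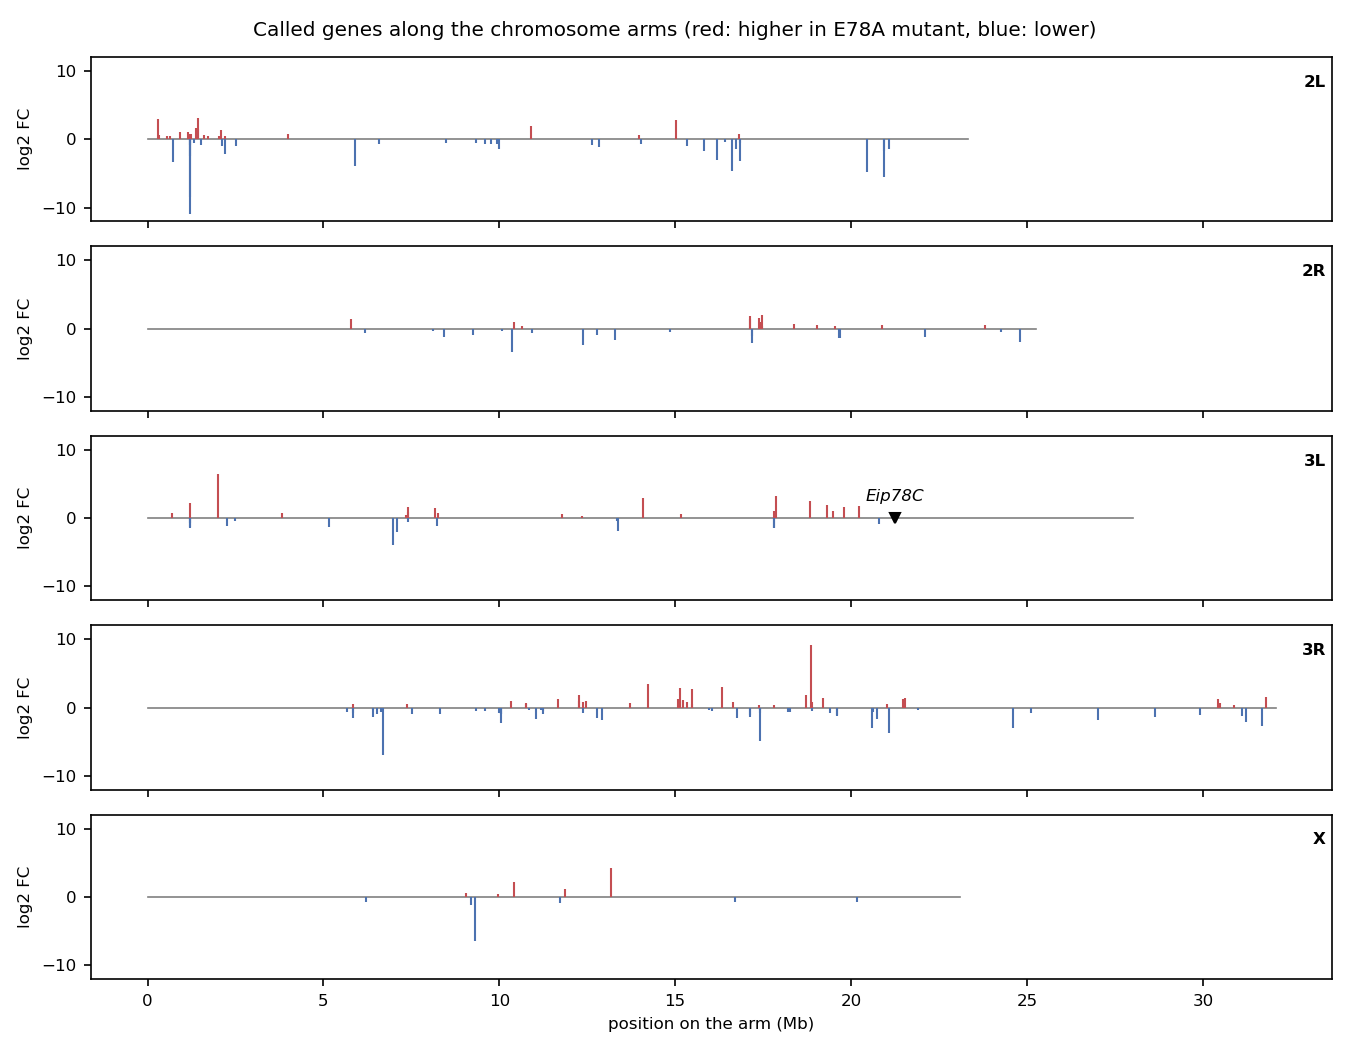
Log2 fold change, mutant over control, of each called gene against its position on the arms 2L, 2R, 3L, 3R and X in Mb, with higher genes in red, lower genes in blue and a triangle at Eip78C. X has 11 called genes and 3R has 85, and both directions occur side by side, as at the start of 2L, where 20 of 237 tested genes in the first 2 Mb were called.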

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

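The tests of depth, mislabelled libraries, midgut tissue and single left-out libraries were chosen after the result they bear on was seen, and the count of splits for the proteases was added after that for the lists was known.

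Chance in how the libraries fall into groups is argued against for the called genes, but cannot be excluded. Of 100 splits of the 9 libraries into 5 and 4, only the real one reached 217 called genes (1 of 100), and the highest other called 32. That split put 4 control libraries against the 4 mutants and the remaining control, so it keeps most of the real contrast. Libraries with the same number in the sample sheet deviate together, so the splits are not all alike. The 10 other drawn splits that part all 4 pairs of the sample sheet called 0 genes with edgeR, with at most 1176 at an unadjusted p under 0.05. Such splits are too few to put the real one under a share of 0.05. For gene lists chance cannot be excluded: 98 of the 100 splits had at least the 3 lists called by camera with the preset correlation, and the highest other had 14.

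The mutated gene itself was not lower in the mutant libraries. Too few reads for a loss to be seen is argued against by the 95% interval, whose lower end of -0.412 excludes a 2-fold loss. Mislabelled libraries are argued against by the first principal component, where 0 libraries lay on the other genotype's side, though this does not exclude both groups being named the wrong way round. Reads of CG43218, the gene inside Eip78C, stay open, since its own counts were 11.5% of those of Eip78C over the mutants, above the bound of 10% set beforehand for ruling them out. A transcript kept outside the altered part of Eip78C may account for the level and stays open, since the table has 1 count row per gene and none per exon.

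The digestive protease list passed camera with a preset correlation and not with an estimated correlation (adjusted p = 0.956). Less midgut tissue in the mutant libraries was tested with the other gut lists, carbohydrate digestion and peritrophic matrix. Their 43 members had a median of -0.0116 (95% bootstrap interval over genes -0.0955 to 0.0778). That lies above -0.175, the proteases' median times 0.5, and by this bound argues against less midgut tissue. But the interval takes genes as independent and leaves out the spread between libraries. The peritrophic matrix sum was lower in the mutant of 3 of the 4 sheet pairs (mean log2 ratio -0.152), the carbohydrate digestion sum in 2. Less midgut tissue thus stays open. A single library is argued against by the medians with 1 library left out, the highest of which was -0.268. Reads shared between near-identical copies are argued against by the 21 members outside the Jonah and trypsin families, with a median of -0.331 (-0.562 to -0.1, likewise an interval over genes). Chance cannot be excluded by the count of splits, 6 of 100 with a median as far from 0 as the real -0.35 and 0.462 the highest other, but 3 of the 5 others replaced 1 mutant library and 2 put most mutant libraries on the other side with the sign reversed, so they carry much of the real contrast.

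A single library stood apart for 15 of the 172 sets of values tested. Chance alone puts the rate near 1 in 20, which is lower than the rate found. In control replicate 4, Eip78C was at 15.6 CPM against 8.57 to 10.4 in the other controls, LysC at 7.67 against 2.74 to 3.85, and Ir75a at 1.98 against 3.48 to 4.07. In control replicate 2, CG34283 was at 0.604 CPM against 1.72 to 1.95, wun2 at 6.59 against 4.82 to 5.14, RpS19a at 525 against 446 to 459, and Ir76a at 2.20 against 3.09 to 3.44. In control replicate 3, Mst84Db was at 131 CPM against 93.2 to 103, ProtB at 111 against 78.5 to 81.2, and esg at 15.01 against 10.2 to 11.4. In mutant replicate 4, Rh6 was at 41.2 CPM against 50.8 to 52.3 in the other mutants, and CG17633 at 136 against 168 to 170. In mutant replicate 1, ImpL3 was at 84.4 CPM against 71.6 to 72 and Muc68D at 524.7 against 327.9 to 347.2, and LysE at 30.0 in mutant replicate 2 against 25.9 to 26.4.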

How the results depend on the processing

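The replicate block, with either correlation, was chosen after seeing the data, and the other settings before. The called genes numbered 94 higher and 123 lower. Leaving out 1 library gave 53 to 139 higher and 74 to 152 lower genes, and every main call that was still tested kept its sign. For 214 of the 217 the libraries of the 2 genotypes do not overlap. Their sign was thus all but fixed in advance, here and with the 5 libraries whose labels agree. The libraries that moved a count by over 1.5 times were mutant replicate 2 (62 higher without it), control replicate 4 (61 higher), mutant replicate 3 (56 higher, 81 lower) and mutant replicate 4 (53 higher, 74 lower). DESeq2 called 235 and 265, the replicate block 248 and 269, the 5 libraries whose labels agree 13 and 8 (19 of the 217 kept, all 217 with the same sign), an adjusted p under 0.01 left 43 and 59, and a 2-fold minimum 44 and 64. With the other scalings and filters the counts stayed between 85 and 95 higher and between 114 and 128 lower.

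Grouped by genotype tag, edgeR called 0 higher and 0 lower genes, 171 had an unadjusted p under 0.05, and 66 of the 217 calls changed sign, since 4 libraries then change sides. Among the named genes followed over the alternatives and called at first, the log2 fold changes that turned were those of CG43401 (-0.089), CR43808 (0.14), CG17192 (0.26), CG13282 (0.084), Mst84Db (-0.12), LysD (0.13) and Ugt36Bc (-0.14). The camera direction turned for the digestive proteases (median -0.0249) and the ribosomal proteins (median -0.00915).

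The 3 called lists became 5 with the replicate block and 0 with an estimated correlation, with or without the block (1 and 0 at an unadjusted p under 0.05). Leaving out 1 library gave 3 or 4, the fourth being heat shock genes (without mutant replicate 2, mutant replicate 3 or control replicate 5, adjusted p from 0.000443 to 0.956 over 20 alternatives) or accessory gland markers (without control replicate 3, 0.0125 to 0.956 over 19). The testis median fell to -0.0682 without control replicate 3. Carbohydrate digestion passed in 2 alternatives, by genotype tag and with the 5 libraries (0.00407 to 0.993). Eip78C stayed uncalled in each setting, and with 1 library left out its log2 fold change ran from -0.0750 to 0.186, its highest without control replicate 4. The calls of CG12374 and CG17633 ended without mutant replicate 3 or 4, that of LysD without control replicate 3 or mutant replicate 4, and that of GstD10 without mutant replicate 4. CG13282 was called in 6 of 16 alternatives that keep the titles' grouping, Mst84Db in 10, IM4 in 9, Ir75a in 8, Ir75b in 10, Cyp4ad1 in 8, Cyp4p2 in 9, Ugt35a in 8 and Ugt36Bc in 10. Uncalled at first, the gene to was called in 4, Fatp and Muc68D in 3, CG18284 in 2, and apolpp, Rh5, CG9458, CG9701, dsf, Eip71CD, fzo and RpL3 in 1 each. The replicate block ended 9 of the 217 calls and added those of CG18284, Npc2a, emp, fabp, CG8628, Npc2h, CG1946, ProtB, apolpp, Rh5, to and Muc68D among the named genes. Of 1986 values of single genes and lists under an alternative, 1772 kept their direction and side of the threshold, 165 lost the call, 40 gained one and 9 turned. Values past no threshold changed sign 26 times. The causes were not tested. At this depth simulated 1.5-fold changes, made in genes of at least 1 CPM among 13274 genes, were recovered in 56.4% of cases, so smaller differences can go uncalled.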

Other observations

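The tests of placement among genes of like expression and of stretches that differ between stocks were chosen after the called genes were seen, as were the gene families and named genes below.

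Of 17 tested ionotropic receptor genes, which detect odours and tastes, Ir76a (1.66, SE 0.17) and Ir100a (1.54, SE 0.19) were higher, and Ir75a (-1.39, SE 0.30) and its neighbour Ir75b (-1.50, SE 0.29) were lower. Of 14 gustatory receptor genes 1 was lower, and none of 9 odorant receptor and 33 odorant-binding protein genes was called. Of 6 lysozyme genes LysC was higher and LysB, LysD and LysE were lower. These 4 lie in 1 cluster, and LysC and LysD overlap on opposite strands. ETH, the ecdysis-triggering hormone, fell from 4.87 ± 1.46 to 1.27 ± 0.418 CPM (-1.94, SE 0.28, edgeR adjusted p = 0.00374), and esg, a transcription factor of intestinal stem cells, from 11.7 ± 1.91 to 5.58 ± 1.218 CPM (-1.07, SE 0.17, edgeR adjusted p = 0.00547).

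Non-coding RNA genes were called more often than protein-coding genes, 41 of 1195 (3.43%) against 171 of 11998 (1.43%). Fisher's exact test, run for this and for the families above, takes genes as independent, which genes lying close together are not, so its p-values are not given. Heat shock levels went with the pairs of the sample sheet: control replicate 5 and mutant replicate 4, which share a number, had the highest sums of their groups, 8393 and 14420 CPM. Of the sterol carrier Npc1b and the triacylglyceride lipase bmm, neither was called (0.22, edgeR adjusted p = 0.6253, and 0.23, edgeR adjusted p = 0.711).

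The authors' deposited table also sorts genes into sets for a DHR39 mutant, another nuclear receptor, whose libraries were not analysed here. In the authors' deposited table, 92 of the 239 genes higher in the E78A mutant (38.5%) were higher in the DHR39 mutant and 25 (10.5%) lower, and 109 of the 267 lower genes (40.8%) were lower there and 12 (4.49%) higher. Independent lists of those sizes over 14562 genes would share 17.6, 28.7, 32.1 and 19.7. Whether both comparisons used the same control libraries is not given in the sources used here. In 20 simulated draws of an unchanged group of 4 libraries against the same controls, edgeR called a median of 0 genes and at most 1, and 0 were shared with the E78A calls in the same direction, while the log2 fold changes correlated at a median of 0.278 through the controls alone. The simulated counts leave out real effects and the independent lists leave out shared controls, so the excess over either cannot be read as a shared effect.

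Called genes lay close together on the chromosomes: 113 of the 217 had another called gene within 100 kb. Chance placement among genes of like expression is argued against by 10000 matched placements, which averaged 72.7 and reached at most 103 (permutation p = 0.0001, one-sided, the smallest they can give). Overlapping genes counted on the same reads are argued against by the 213 genes left without called genes that overlap another, of which 107 had a neighbour against a mean of 70.3 and a highest of 108 over the placements (permutation p = 0.0002). Stretches of chromosome that differ between the 2 stocks may account for it and cannot be told apart from an effect of E78A, because stock and genotype coincide and counts hold no sequence. The low share on X, 0.541%, the 49 of 77 neighbouring pairs with the same sign, and the 1 call of 265 genes around Eip78C are values that such a test would start from.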
